A study of Arabidopsis thaliana with 12 samples.

How the data were processed

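Whole seedlings of 4 Arabidopsis genotypes were sampled, 3 libraries each: WT (Col-0), pnet2_ac, pnet2_bc and pnet2_abc. Per the labels' protocols, seedlings grew on half-strength MS medium with 1% sucrose and were taken at 7 days, RNA came from some 50 mg of plants with a commercial kit, and strand-specific mRNA libraries were sequenced as paired reads on an Illumina HiSeq. Sample groups and replicate numbers come from the sample titles.

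The deposited count table holds whole-number read counts per gene, not normalized, for 27436 genes in the 12 libraries. Per the submitters' processing notes, the build was TAIR10 and HISAT2 2.0.4 and HTSeq 0.6.1p1 were used; their roles, their options and the strand setting of the counting are not given in the sources used here. HTSeq, if it made the counts, would leave out or assign reads of overlapping genes by rules that are not known here. Reads from a gene and an antisense gene over the same bases therefore cannot be told apart. Named genes with opposite-strand overlaps of at least 301 bases are marked in the text. Shorter ones concern WRKY33 (272 and 26 bases), RVE1 (225), RLP22 (175), PAP17 (122), P5CS1 (91), DIN10 (82), ADH1 (61), WRKY40 (51), CYCA2;3 (48), PRK (33), FRO3 (24), ABI1 (22) and AT3G05640 (8). On the same strand AT1G29785 (169), FBA5 (109), AT1G22882 (41) and AT1G66100 (30) overlap another gene. The deposited TPM table holds TPM values (transcript abundance scaled to a fixed sum) per gene for the same 27436 genes, from kallisto per the file name, with its version and transcript index not given. Each library's TPM values sum to 1000000 over the listed genes. How transcripts were combined per gene is not stated in the file headers.

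Totals were 65758625 to 115881203 counts per library, with pnet2_ac replicate 1 the deepest. A gene with no count in a library could be present at up to 3 counts, 0.0262 to 0.0436 CPM on the TMM-adjusted scale defined below, and this floor covers counting error only. Replicate libraries differed by far more than sampling noise (chi-square per degree of freedom 31.18 to 48.89 within groups), so each was kept as 1 replicate. Of the gene IDs, 27173 matched the reference annotation of TAIR10.1, which gave symbols, coordinates, exons and overlaps, and the other 263 were organelle genes. TAIR10.1 is not the build named by the submitters, so coordinates are given as those of TAIR10.1 and only gene IDs join it to the counts.

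The counts were analysed in R 4.3.3 with edgeR 4.0.16: genes kept by filterByExpr (23330), TMM scaling, 1 quasi-likelihood model with a mean per genotype over all 12 libraries and 8 residual degrees of freedom. The 6 pairwise comparisons were tested with glmQLFTest and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. CPM values are counts scaled to a TMM-adjusted library size of 1000000, given as mean ± SD over 3 libraries, and fold changes are given on the log2 scale with SE from the test statistic, or as a fold. Where a group had no count, the fold is a lower bound against 3 counts over that group. Counts were also simulated for the same genes at their WT means, with 50 genes changed at each fold in the mutant group. The changed genes had a WT mean of at least 1 CPM, so the shares do not cover lower genes. Of 2-fold rises, 82%, 76% and 80% were called for pnet2_ac, pnet2_bc and pnet2_abc against WT (22353, 22359 and 22372 genes tested). The shares were 76%, 80% and 86% for 2-fold falls, 44%, 42% and 48% for 1.5-fold rises and 92%, 96% and 92% for 4-fold rises. Of the calls, 2.6%, 3.3% and 3.2% were false. Most tested genes were called in the real pnet2_abc libraries, so the simulated shares do not describe that comparison.

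Before the data were examined, the model, the alternatives, 26 gene lists and the rule for naming genes were fixed. The lists covered salicylic acid and systemic immunity, pattern-triggered immunity and camalexin, jasmonate and ethylene defence, abscisic acid and drought, cold, low oxygen, heat shock, the unfolded protein response, oxidative and mitochondrial stress, senescence, photosynthesis, auxin response, cell wall loosening, cell cycle, DNA damage, nuclear envelope and lamina, floral, embryo and meristem regulators, phosphate starvation, iron homeostasis, anthocyanin and flavonol, aliphatic glucosinolate, the circadian clock, and markers of root identity, root hairs, the stomatal lineage and seed maturation. Of 533 members, 1 was dropped because the reference gives its symbol to another locus and 1 was not in the table. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over 78 tests, and again with the correlation estimated. List medians did not change when members without a count in 1 group were set to their bound.

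For each comparison with WT the named genes were the 3 targeted genes, the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM over all 12 libraries and no overlap between the libraries of the 2 groups, and the called members with the smallest p, up to 3 of each list that passed and 1 of each other list. Between mutants the 4 largest rises and falls were named by the same rule. Transcripts of named genes were compared with all reference transcripts with BLAST+ 2.17.0, and a copy was called near-identical at 95% identity over 80% of the length. Centromere centres were estimated as the middle of the gene-poorest 2 Mb window of each chromosome. No-effect values for comparisons that share the WT libraries came from 20 simulations.

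Alternatives were DESeq2's size factors in the edgeR model, library size without composition factors, no low-count filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0 (Wald test), only the 6 libraries compared, robust dispersions, the replicate number as a block, each library left out in turn, and limma on log2 of the deposited TPM plus 1 (genes with a mean TPM of at least 1), plus 0.1, or without that filter. For the positions of called genes the alternatives were limits of 2 and 5 Mb and calls of at least 1 log2 unit, and for the shared response genes with a mean of at least 5 CPM. Changes on the log2(TPM + pseudocount) scale understate those of low genes. Python 3.11.15 was used for the genome positions and the plots.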

Results

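Messenger RNA was measured by RNA sequencing in whole Arabidopsis thaliana seedlings, 7 days old and untreated, that were wild type (ecotype Col-0, here WT) or carried mutations in genes for the nuclear membrane proteins PNET2A, PNET2B and PNET2C. The 4 genotypes were WT, the double mutants pnet2_ac and pnet2_bc, and the triple mutant pnet2_abc, with 3 libraries each and 12 in all. Counts over the 27436 listed genes summed to between 65758625 and 115881203 per library. At that depth 3 counts in a library corresponded to 0.0262 to 0.0436 normalised counts (CPM, counts scaled to a TMM-adjusted library size of 1000000), and 23330 genes had enough counts to be tested. The labels do not say whether the libraries of a genotype came from separate sets of plants, so p-values measure only the spread between these libraries.

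The genes that the mutations should affect were examined first. The reference names no gene PNET2, and the 3 genes it annotates with the domain DUF2215 were taken as the targeted family; which of them is A, B or C was not given in the sources used here. In coordinates of the assembly TAIR10.1 these were AT1G28760 on chromosome 1 (10103081 to 10104883, plus strand, 1 exon), AT3G49840 on chromosome 3 (18484513 to 18487043, plus strand, 9 exons) and AT5G67610 on chromosome 5 (26960904 to 26963736, minus strand, 10 exons), all protein-coding. Counts over a whole gene can include transcripts of a mutant allele, so a level near WT does not contradict a genotype label.

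In pnet2_abc, transcripts of AT3G49840 and AT5G67610 were lower than in WT and transcripts of AT1G28760 were higher. AT3G49840 fell from 9.36 ± 1.36 CPM in WT to 2.17 ± 0.13 CPM (SD, n = 3), a log2 fold change of -2.11 ± 0.18 (SE, adjusted p = 3.1e-07). AT5G67610 fell from 21.6 ± 2.46 to 11.2 ± 0.71 CPM (log2 fold change -0.95 ± 0.10, adjusted p = 2.4e-06). AT1G28760 rose from 3.97 ± 0.44 to 47.4 ± 5.995 CPM, 11.9-fold (log2 fold change 3.58 ± 0.14, adjusted p = 2.4e-10). In pnet2_ac none of the 3 passed the test: the means were 5.33 ± 0.52, 6.69 ± 0.54 and 22.5 ± 1.59 CPM for AT1G28760, AT3G49840 and AT5G67610, with adjusted p of 0.154, 0.209 and 0.863. In pnet2_bc, AT5G67610 fell to 14.8 ± 0.55 CPM (log2 fold change -0.55 ± 0.10, adjusted p = 0.032), while AT1G28760 stood at 4.44 ± 0.55 CPM and AT3G49840 at 6.81 ± 1.44 CPM (adjusted p 0.750 and 0.329). That call for AT5G67610 in pnet2_bc was lost, with adjusted p of 0.104, 0.121, 0.135, 0.0943 and 0.0814, when WT replicate 1, WT replicate 3 or pnet2_bc replicate 1, 2 or 3 was left out.

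**Figure D1:**
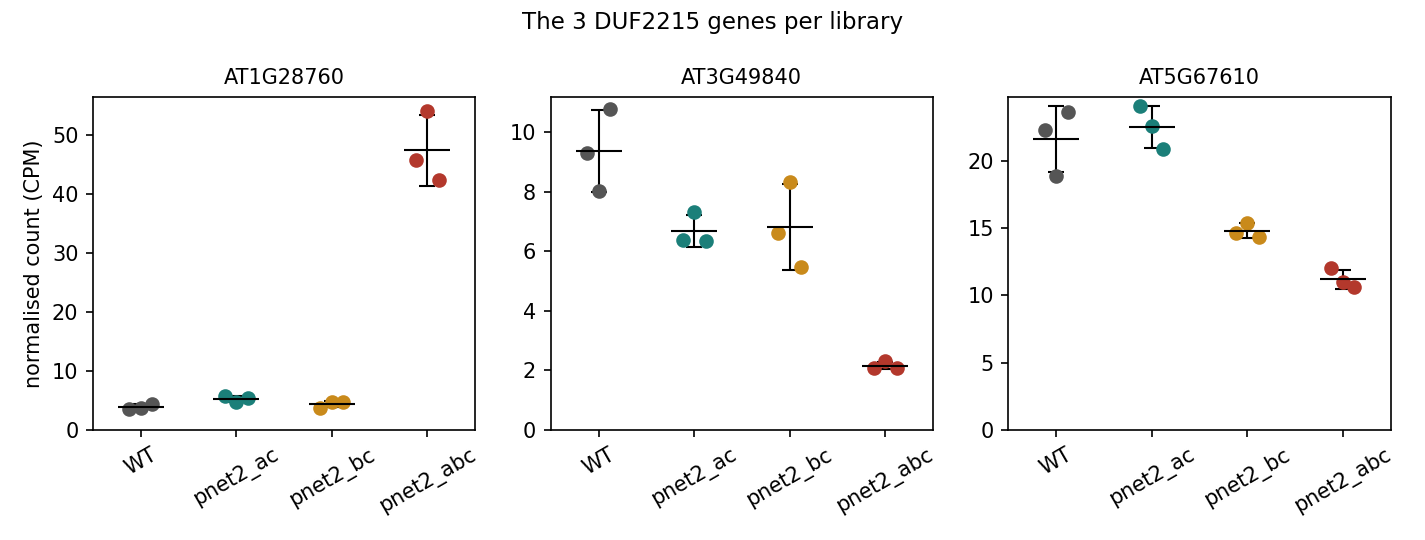
Normalised counts (CPM, vertical axis) of the 3 DUF2215 genes in each library of WT, pnet2_ac, pnet2_bc and pnet2_abc, with points for libraries and bars for mean and SD (n = 3). AT1G28760 lies at 42.4 to 54.1 CPM in pnet2_abc and under 6 CPM in the other 9 libraries, while AT3G49840 has its lowest values in pnet2_abc.

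Across all genes, pnet2_abc stood far from the other 3 genotypes. The first principal component carried 64.3% of the variance and placed the 3 pnet2_abc libraries at 166 to 190 and the other 9 at -69.0 to -45.4. Against WT, edgeR's quasi-likelihood test called 15054 genes in pnet2_abc (Benjamini-Hochberg adjusted p under 0.05), 7587 higher and 7467 lower, of which 7917 differed at least 2-fold. The same test called 266 genes in pnet2_ac (105 higher, 161 lower, 49 at least 2-fold) and 150 in pnet2_bc (70 higher, 80 lower, 35 at least 2-fold). The double-mutant counts moved with the test and the libraries: DESeq2 called 1101 and 680 genes, and leaving out both WT replicate 1 and pnet2_ac replicate 2, chosen after the principal components were seen because they lay farthest from their groups, left 17 and 67.

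**Figure D2:**
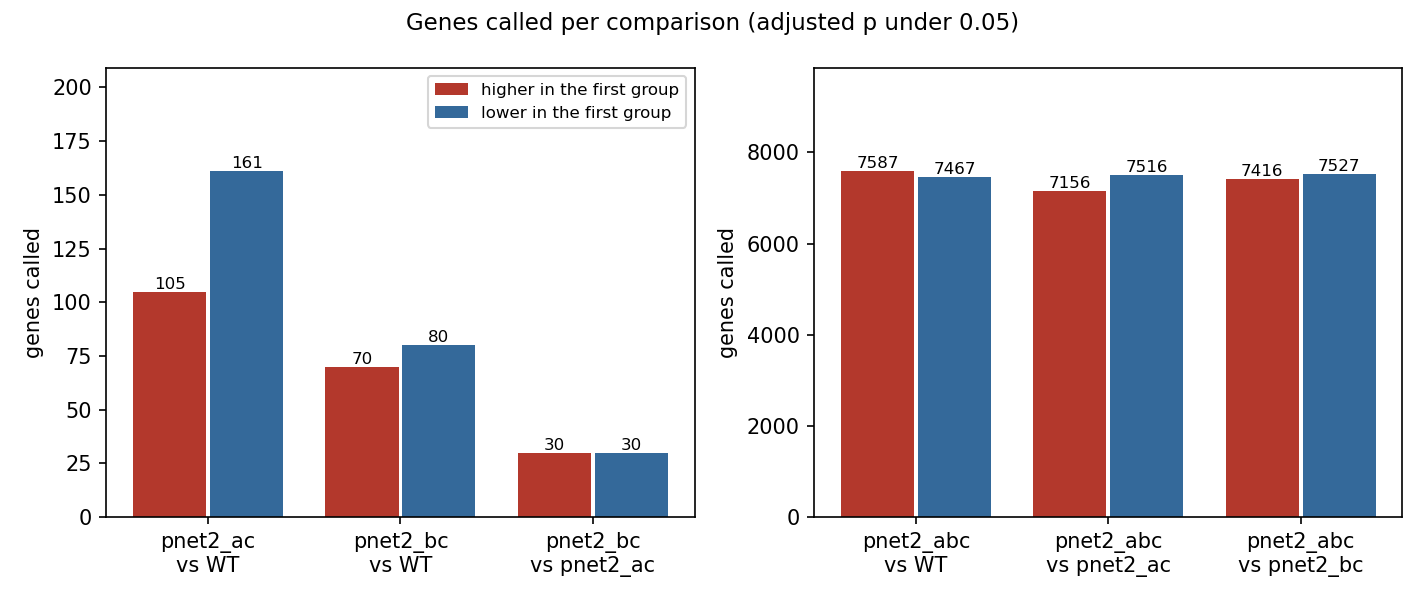
Number of genes called (adjusted p under 0.05, edgeR quasi-likelihood test) in each of the 6 comparisons, split into those higher and those lower in the first genotype named; the panels have separate vertical axes. The comparisons with pnet2_abc called between 14672 and 15054 genes and the others between 60 and 266.

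The split into higher and lower genes depended on how the libraries were scaled. Under TMM scaling 39.5% of the called genes were higher in pnet2_ac, 46.7% in pnet2_bc and 50.4% in pnet2_abc. With library size alone these shares were 67.6%, 61.0% and 60.2%, and with the deposited TPM values they were 59.5 to 69.8%, 58.1 to 60.4% and 60.5 to 63.0%. Library size alone moved the median log2 fold change of all genes in pnet2_abc from 0.01 to 0.205, and fold changes in the text are relative to the TMM scaling.

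The comparison of pnet2_ac with WT asked what differs in seedlings with mutations in A and C. WIP1 (AT4G26455, chromosome 4, 13365283 to 13367531), which encodes a WPP domain-interacting protein of the nuclear envelope, rose 15.9-fold, from 20.6 ± 2.23 CPM in WT to 327 ± 50.4 CPM (log2 fold change 3.99 ± 0.12, adjusted p = 3.0e-09). MRD1 rose 4.17-fold to 48.2 ± 5.04 CPM, the receptor-like kinase gene AT1G35710 rose 4.01-fold to 18.5 ± 3.64 CPM, and the receptor kinase gene CRK6 rose 5.64-fold to 1.51 ± 0.55 CPM. RD20, a stress-induced caleosin gene, rose 4.63-fold, with 49.4 CPM in pnet2_ac replicate 1 against 13.9 and 15.8 CPM in replicates 2 and 3. AT4G12735, of unknown function, rose from 0.0422 to 0.460 CPM, with its WT mean at the floor of 3 counts per library. CRK6 stood at 0.108 to 0.368 CPM in WT. Both genes reached the mean of 5 CPM needed for naming only through pnet2_abc.

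Among the named genes that fell in pnet2_ac, the non-coding AT1G67105 had the largest change, from 36.8 ± 26.6 CPM in WT, where its libraries ranged from 13.2 to 65.7 CPM, to 0.885 ± 0.34 CPM (log2 fold change -5.39 ± 0.50, adjusted p = 0.00058). AT1G61690, annotated as a phosphoinositide-binding protein, fell 3.35-fold to 9.16 ± 1.21 CPM. MYBL2, a repressor of anthocyanin synthesis, fell 2.41-fold to 14.5 ± 3.15 CPM, AT3G62070 fell 2.29-fold, AT1G53625 fell 3.64-fold, and the long non-coding AT1G29785, which overlaps an antisense gene over 666 bases, fell 4.27-fold. AT1G53625 and AT1G29785 also reached the mean of 5 CPM needed for naming only through pnet2_abc. Antisense genes overlap MRD1 over 1446 and 1039 bases, so its counts cannot be told apart from theirs without the strand setting of the counting. Of the 23 named genes called in pnet2_ac, 8 kept their call when any single library was left out, and 4 kept it in all alternatives (WIP1, AT1G35710, AT1G67105 and AT1G61690). The highest adjusted p among the other 15 with a library left out was 0.144.

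Several gene lists fixed before the data were examined passed camera with the preset correlation in pnet2_ac, by small amounts per gene, and none of them passed with an estimated correlation (adjusted p 0.231 to 0.525). Lists for oxidative and mitochondrial stress (20 tested members, median log2 fold change 0.81, camera adjusted p = 8.2e-08), anthocyanin and flavonol (14 members, 0.66, 0.00059), salicylic acid and systemic immunity (25, 0.43, 2.4e-05), jasmonate and ethylene defence (27, 0.27, 0.00038), the unfolded protein response (17, 0.25, 1.6e-05), phosphate starvation (14, 0.24, 0.0159) and cold response (14, 0.17, 0.0144) were higher. The photosynthesis list (46 members, median -0.17, adjusted p = 2.1e-10), the auxin response list (31, -0.38, 3.7e-08) and the iron homeostasis list (17, -0.54, 0.00054) were lower. The nuclear envelope and lamina list passed upward (29 members, adjusted p = 0.007) with a median of -0.01 and a mean of 0.15, and WIP1 was its single called member. With an estimated correlation adjusted p was 0.251 for oxidative stress, the unfolded protein response and the nuclear envelope, 0.288 for salicylic acid, jasmonate and cold, 0.340 for anthocyanin, 0.525 for phosphate, 0.348 for photosynthesis, 0.231 for auxin and 0.307 for iron. The cold call was also lost without WT replicate 3 (adjusted p = 0.0719) or pnet2_ac replicate 1 (0.0928), the nuclear envelope call without WT replicate 3 (0.0719), with no low-count filter (0.0774) or with a replicate block (0.535), and the phosphate call without WT replicate 1 (0.0692) or 2 (0.158). Over the alternatives with the preset correlation, adjusted p ran from 0.00134 to 0.0928 for cold, 0.000204 to 0.535 for the nuclear envelope and 4.7e-05 to 0.158 for phosphate. The iron call was lost when WT replicate 1 and pnet2_ac replicate 2 were both left out (0.0798, range 6.5e-07 to 0.0798).

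Few members of these lists passed the test one by one in pnet2_ac. In the jasmonate list VSP2, which encodes a vegetative storage protein, rose 3.11-fold and AOC2, of jasmonate synthesis, rose 2.59-fold, and 25 members were not called. WAK1, a wall-associated kinase gene, was the single called member of the salicylic acid list and rose 3.05-fold. No member was called in the oxidative stress, unfolded protein, cold and phosphate lists, and RD20 was the single called member of the abscisic acid list. In the photosynthesis list PRK, the phosphoribulokinase of the Calvin cycle, fell from 1605 ± 58.3 to 1235 ± 41.1 CPM (log2 fold change -0.38 ± 0.05) and 45 members were not called. The auxin-induced SAUR15 and IAA1 fell 3.45-fold and 1.87-fold, and PYE, a regulator of the iron deficiency response, fell 1.67-fold. MYBL2 was the single called member of the anthocyanin list and was lower. It encodes a repressor of anthocyanin synthesis, so its fall does not contradict the list's rise. Adjusted over the list alone, 10 of 20 oxidative stress members, 7 of 25 salicylic acid members, 7 of 17 unfolded protein members, 5 of 27 jasmonate members, 5 of 14 anthocyanin members (1 lower) and 2 of 14 cold members were higher, and 16 of 46 photosynthesis members, 9 of 31 auxin members and 4 of 17 iron members (1 higher) were lower.

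The other 15 lists did not pass in pnet2_ac (adjusted p from 0.0576 for senescence to 0.965 for seed maturation markers). From them the rule for naming genes took ERF6 (1.94-fold higher), XTH24 (1.45-fold lower), the MADS-box gene MAF5 (2.07-fold higher) and CCR1, the clock-regulated RNA-binding protein GRP8 (1.32-fold higher). Median, mean and test went different ways for cell wall loosening (median 0.04, mean -0.05) and for floral, embryo and meristem regulators (-0.02 and 0.25).

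In pnet2_bc, compared with WT for mutations in B and C, 4 of 23 tested genes of the abscisic acid and drought list rose and 19 were not called. RD20 rose 7.60-fold to 43.4 ± 11.7 CPM (log2 fold change 2.93 ± 0.42, adjusted p = 0.0107), HAI1, a protein phosphatase of abscisic acid signalling, rose 4.50-fold to 25.7 ± 8.41 CPM, and P5CS1, of proline synthesis, rose 2.28-fold from 113 ± 10.3 to 256 ± 27.8 CPM. The list had a median of 0.55 with no member called lower, and 13 were higher when adjusted over the list alone (camera adjusted p = 2.8e-15; adjusted p = 0.231 with an estimated correlation). Jasmonate-responsive VSP2 and CORI3 rose 4.39-fold and 3.58-fold, the phosphatase gene AT3G05640 3.28-fold and AT1G69480, of the EXS family, 3.08-fold. The WIP1 mean was 20.9 ± 0.73 CPM, against 20.6 ± 2.23 in WT.

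Among the named genes, MRD1 and 2 non-coding genes fell most in pnet2_bc. MRD1 fell 20.7-fold, from 11.5 ± 1.38 to 0.549 ± 0.43 CPM, the opposite direction to pnet2_ac. AT1G67105 fell 22.2-fold to 1.65 ± 0.12 CPM. AT3G22121, which lies wholly antisense within AT3G22120, fell from 42.4 ± 29.1 to 4.24 ± 0.78 CPM, with 8.80 CPM in WT replicate 1 against 57.6 and 60.8 CPM in the other 2 WT libraries. AT1G53625 fell 4.11-fold, AT2G17740 fell 3.03-fold and the peroxidase gene PER4 fell 2.40-fold. These last genes, AT1G53625, AT2G17740 and PER4, reached the mean of 5 CPM needed for naming only through pnet2_abc. Of the 23 named genes called in pnet2_bc, 6 kept their call in all alternatives (AT1G67105, MRD1, WRKY33, WRKY22, P5CS1 and XTH24). The other 17 were lost with at least 1 single library left out, at adjusted p of up to 0.181.

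The pattern-triggered immunity list fell in pnet2_bc (24 members, median -0.19, adjusted p = 1.4e-05; adjusted p = 0.196 with an estimated correlation). WRKY33, a transcription factor of pathogen responses, fell 1.79-fold, WRKY22 fell 2.07-fold and ERF104 fell 1.72-fold, 4 members were called lower in all, and adjusted over the list alone 5 were lower and 1 higher. The jasmonate list was higher (27 members, median 0.25, adjusted p = 1.4e-05; adjusted p = 0.251 with an estimated correlation), with VSP2, AOC2 (2.49-fold) and CORI3 called and 6 members higher when adjusted over the list alone. In the cold response list (14 members, median 0.50, adjusted p = 0.00167; adjusted p = 0.251 with an estimated correlation) the dehydrin gene ERD10 rose 2.15-fold and the zinc finger gene STZ fell 2.25-fold. In the iron list (17, median -0.42, adjusted p = 0.00276; adjusted p = 0.348 with an estimated correlation) PYE fell 1.75-fold and FRO3, a ferric reductase gene, fell 1.40-fold. Over the list alone 5 cold members were higher and 1 lower, and 4 iron members were lower. XTH24, a cell wall xyloglucan enzyme gene, fell 1.65-fold.

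Lists for anthocyanin (14 members, median 0.49, adjusted p = 1.9e-05) and oxidative stress (20, 0.21, 0.0464) were higher in pnet2_bc, and lists for photosynthesis (46, -0.06, 0.0116), auxin response (31, -0.19, 0.0178), phosphate starvation (14, -0.36, 0.00321) and the clock (19, -0.19, 0.0106) were lower, with no member called over all genes. Over the list alone 4 anthocyanin members were higher, 2 auxin, 1 photosynthesis and 1 phosphate members were lower, the clock had 1 each way and oxidative stress none. With an estimated correlation their adjusted p values were 0.288, 0.525, 0.736, 0.386, 0.415 and 0.251. Single libraries also ended 5 of these calls: oxidative stress without WT replicate 1 (0.256) or 3 (0.0719), pnet2_bc replicate 2 (0.894, where the median turned to -0.04) or pnet2_abc replicate 2 (0.0521); photosynthesis without WT replicate 3 (0.370) or pnet2_bc replicate 2 (0.293); auxin without WT replicate 1 (0.0741) or pnet2_bc replicate 1 (0.0960) or 2 (0.0804); phosphate without WT replicate 3 (0.257) or pnet2_bc replicate 1 (0.0679); and the clock without WT replicate 1 (0.0819). For each of the 5 the largest of these values (0.894, 0.370, 0.0960, 0.257 and 0.0819) was the highest adjusted p over the alternatives with the preset correlation, and the lowest were 0.00053, 0.00153, 6.5e-05, 2.5e-06 and 0.00219. A stricter filter of 5 CPM ended the calls for cold (0.0878, range 3.0e-05 to 0.0878), oxidative stress (0.0557) and auxin (0.0678), and library size alone those for oxidative stress (0.0871) and photosynthesis (0.0530). The other 15 lists had adjusted p of 0.0704 to 0.965, and median, mean and test went different ways for root identity markers (median -0.11, mean 0.27), for heat shock (0.06 and 0.37, tested as lower) and for seed maturation markers (-1.46 and -0.83, tested as higher).

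**Figure D3:**
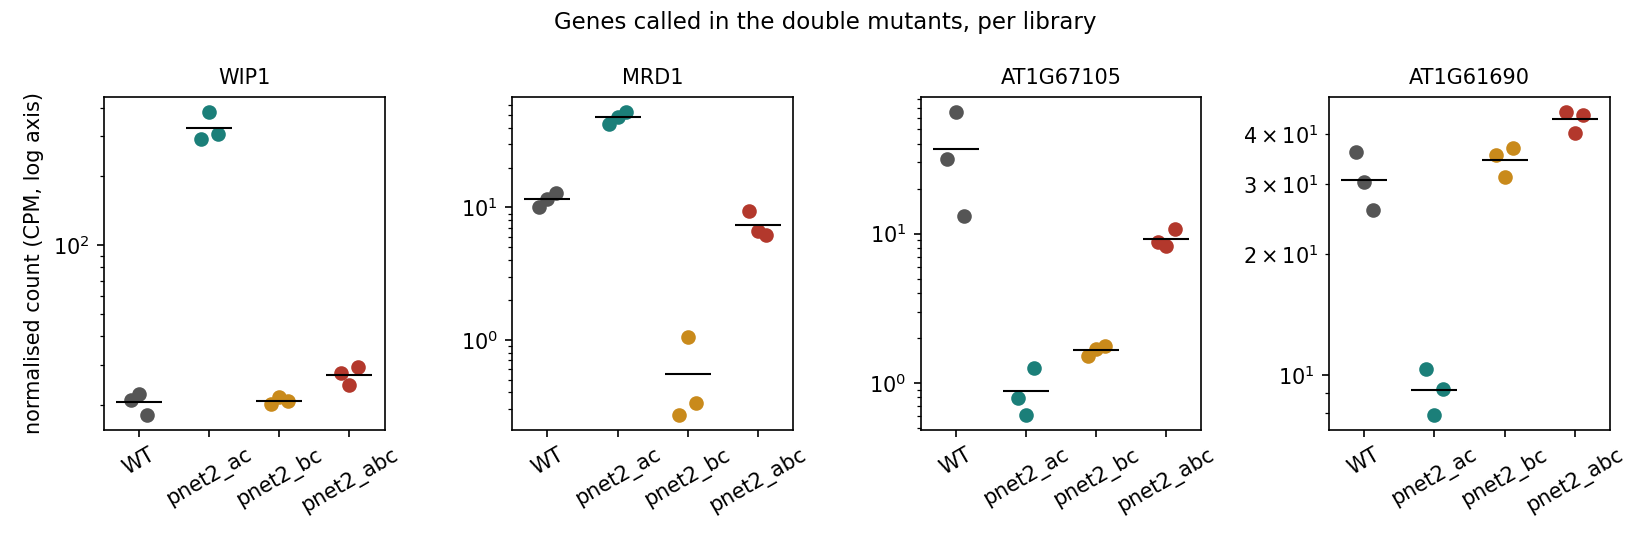
Normalised counts (CPM, log axis) per library of genes called in the double mutants, with a line at each group mean. WIP1 lies at 290 to 384 CPM in the 3 pnet2_ac libraries and at 18.1 to 29.2 CPM in the other 9, and MRD1 is highest in pnet2_ac and lowest in pnet2_bc.

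The triple mutant, compared with WT for mutations in all 3 genes, differed in genes of photosynthesis, cell division, defence and low-oxygen metabolism. Of all 23330 tested genes 7587 were called higher and 7467 lower in pnet2_abc, so many members of any list would be called. All 46 tested photosynthesis genes fell, with a median log2 fold change of -2.11 (camera adjusted p = 1.4e-54; adjusted p = 0.196 with an estimated correlation). PRK fell 4.78-fold from 1605 ± 58.3 to 336 ± 9.36 CPM, DRT112, a plastocyanin gene, fell 4.28-fold from 3180 ± 113 to 743 ± 40.6 CPM, and PETE1, the other plastocyanin, fell 6.22-fold. The composition of the libraries differed as well: the 10 most abundant genes of a library took 3.58 to 3.83% of counts in pnet2_abc and 6.97 to 8.08% in the other 9 libraries. Genes annotated as ribosomal RNA took 0.365 to 0.475% against 0.0955 to 0.117%, and organelle genes 0.048 to 0.064% against 0.078 to 0.112%.

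Defence genes rose together in pnet2_abc. Of 24 pattern-triggered immunity genes 23 rose and none fell (median 2.64, adjusted p = 2.9e-10; adjusted p = 0.0891 with an estimated correlation), among them WRKY33 (6.29-fold, to 183 ± 17.3 CPM), WRKY40 (29.6-fold) and the transporter PEN3 (5.80-fold, to 756 ± 18.5 CPM). Of 25 salicylic acid genes 19 rose and 2 fell (median 2.06, adjusted p = 0.00049; adjusted p = 0.340 with an estimated correlation), with WRKY18 15.9-fold, SAG101 9.88-fold and SARD1, which overlaps an antisense gene, 58.3-fold higher. The jasmonate list had 19 members higher and 4 lower of 27 (median 1.54, adjusted p = 0.0022; adjusted p = 0.340 with an estimated correlation), and the repressor gene JAZ1 and the lipoxygenase genes LOX4 and LOX3 rose 26.3-fold, 19.7-fold and 16.0-fold.

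Genes of low-oxygen and mitochondrial stress metabolism rose as well. Of 17 low-oxygen genes 16 rose (median 3.09, adjusted p = 9.8e-08; adjusted p = 0.307 with an estimated correlation). ADH1, the alcohol dehydrogenase of fermentation, went from 9.93 ± 2.61 to 1174 ± 274 CPM, 118-fold, SUS1, a sucrose synthase gene, rose 8.53-fold and AlaAT1, an alanine aminotransferase gene, rose 5.14-fold. The oxidative and mitochondrial stress list had 13 of 20 members higher and 2 lower (median 2.94, adjusted p = 0.0022; adjusted p = 0.354 with an estimated correlation), with BCS1, an outer mitochondrial membrane protein gene also named OM66, 102-fold higher (log2 fold change 6.68), AOX1A, the alternative oxidase, at 3.04 and the cytochrome P450 gene CYP81D8 at 4.64. In the cold list 9 of 14 members rose and 1 fell (median 1.33, adjusted p = 0.00335; adjusted p = 0.251 with an estimated correlation), with STZ 25.4-fold, RHL41, also named ZAT12, 19.0-fold and ERD10 8.05-fold higher. The unfolded protein list had 15 of 17 higher and 1 lower (median 0.70, adjusted p = 0.00167; adjusted p = 0.340 with an estimated correlation), among them the transcription factor gene BZIP60 (4.84-fold), PDIL1-1 (2.82-fold) and BIP1 (1.97-fold), whose transcript is 97.2% identical to BIP2 over 74.6% of its length.

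Genes of cell division, auxin response and stomatal development fell in pnet2_abc. Of 36 cell cycle genes 32 fell and 1 rose (median -1.51, adjusted p = 1.4e-07; adjusted p = 0.251 with an estimated correlation): SYP111, the cytokinesis syntaxin KNOLLE, fell 5.33-fold, the cyclin gene CYCA2;3 4.51-fold and CDC20.2, which shares 97.0% identity over 70.4% of its length with CDC20.1, 4.43-fold. Of 31 auxin genes 23 fell and 2 rose (median -2.69, adjusted p = 3.0e-05; adjusted p = 0.251 with an estimated correlation), and SHY2 (IAA3), ATAUX2-11 (IAA4) and IAA14 fell, with log2 fold changes of -3.59, -2.44 and -3.98. SHY2 and SYP111 each overlap an antisense gene. All 6 stomatal lineage genes fell (median -1.67, adjusted p = 0.0441; adjusted p = 0.340 with an estimated correlation), TMM 4.55-fold, SPCH 5.72-fold and EPF2 4.40-fold. That stomatal call was lost without pnet2_abc replicate 1 (0.0502) or 2 (0.0510), with only the 6 libraries compared (0.0571) and with the filter of 5 CPM (0.0836), within a range of 0.0224 to 0.0836 over the alternatives.

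DNA damage genes rose, with 12 of 19 higher and 1 lower (median 0.99, adjusted p = 0.00232; adjusted p = 0.251 with an estimated correlation), among them GMI1, NAC044 and PARP2 (log2 fold changes 3.71, 4.13 and 1.73). The senescence list had 8 of 13 members higher and 4 lower (median 1.39, adjusted p = 0.0194; adjusted p = 0.266 with an estimated correlation). In it WRKY6 rose 5.14-fold and NYC1, of chlorophyll breakdown, 2.71-fold, while DIN10, a dark-induced raffinose synthase gene, fell 3.56-fold. Iron homeostasis genes fell, 14 of 17 (median -2.83, adjusted p = 0.0186; adjusted p = 0.415 with an estimated correlation), with the iron transporter gene IRT1 54.2-fold, NAS4 7.10-fold and BTS 3.35-fold lower. Aliphatic glucosinolate genes fell too, 13 of 16 (median -2.22, adjusted p = 1.2e-08; adjusted p = 0.266 with an estimated correlation), with MYB29 53.0-fold, BAT5 6.09-fold and CYP83A1 5.90-fold lower. The filter of 5 CPM ended the calls for senescence (0.0509, range 0.0135 to 0.0509) and iron (0.144, range 0.00279 to 0.144). Adjusted over the list alone the counts for lists called in pnet2_abc were the same, except 20 members higher in the salicylic acid list and 9 in the senescence list.

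In the 11 lists that did not pass in pnet2_abc (adjusted p 0.102 to 0.973), called members went both ways in 8. For abscisic acid 10 of 23 were higher and 7 lower (median 0.21), for cell wall loosening 8 and 13 of 25 (-0.41), for heat shock 4 and 8 of 20 (-0.28), for the nuclear envelope 11 and 8 of 29 (-0.01) and for floral, embryo and meristem regulators 6 and 5 of 21 (0.06). For phosphate they were 4 and 5 of 14 (0.01), for anthocyanin 8 and 3 of 14 (1.55) and for the clock 7 and 7 of 19 (median 0.13, mean -0.27). Examples were ABI1 (2.83-fold higher), HSFA7A (3.84-fold lower), AT1G22882, also named SUN3 (2.38-fold higher), AGL20, also named SOC1 (3.44-fold lower), PAP17 (2.93-fold higher) and MYBL2 (8.55-fold lower). XTH24 rose 15.9-fold, from 66.2 ± 1.54 to 1052 ± 64.0 CPM, although it fell in both double mutants. Root identity markers had none of 14 members higher and 4 lower (median -0.34, SHR 2.94-fold lower), root hair markers 1 of 8 higher (median 0.00, mean 0.13) and seed maturation markers none of 3 called. The 1 root hair gene, RHD6 (1.61-fold higher, adjusted p = 0.0499), lost its call in 16 of 23 alternatives. It was the only exception among the 70 named genes called in pnet2_abc, though AT3G25830 had no value in DESeq2's Wald test.

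**Figure D4:**
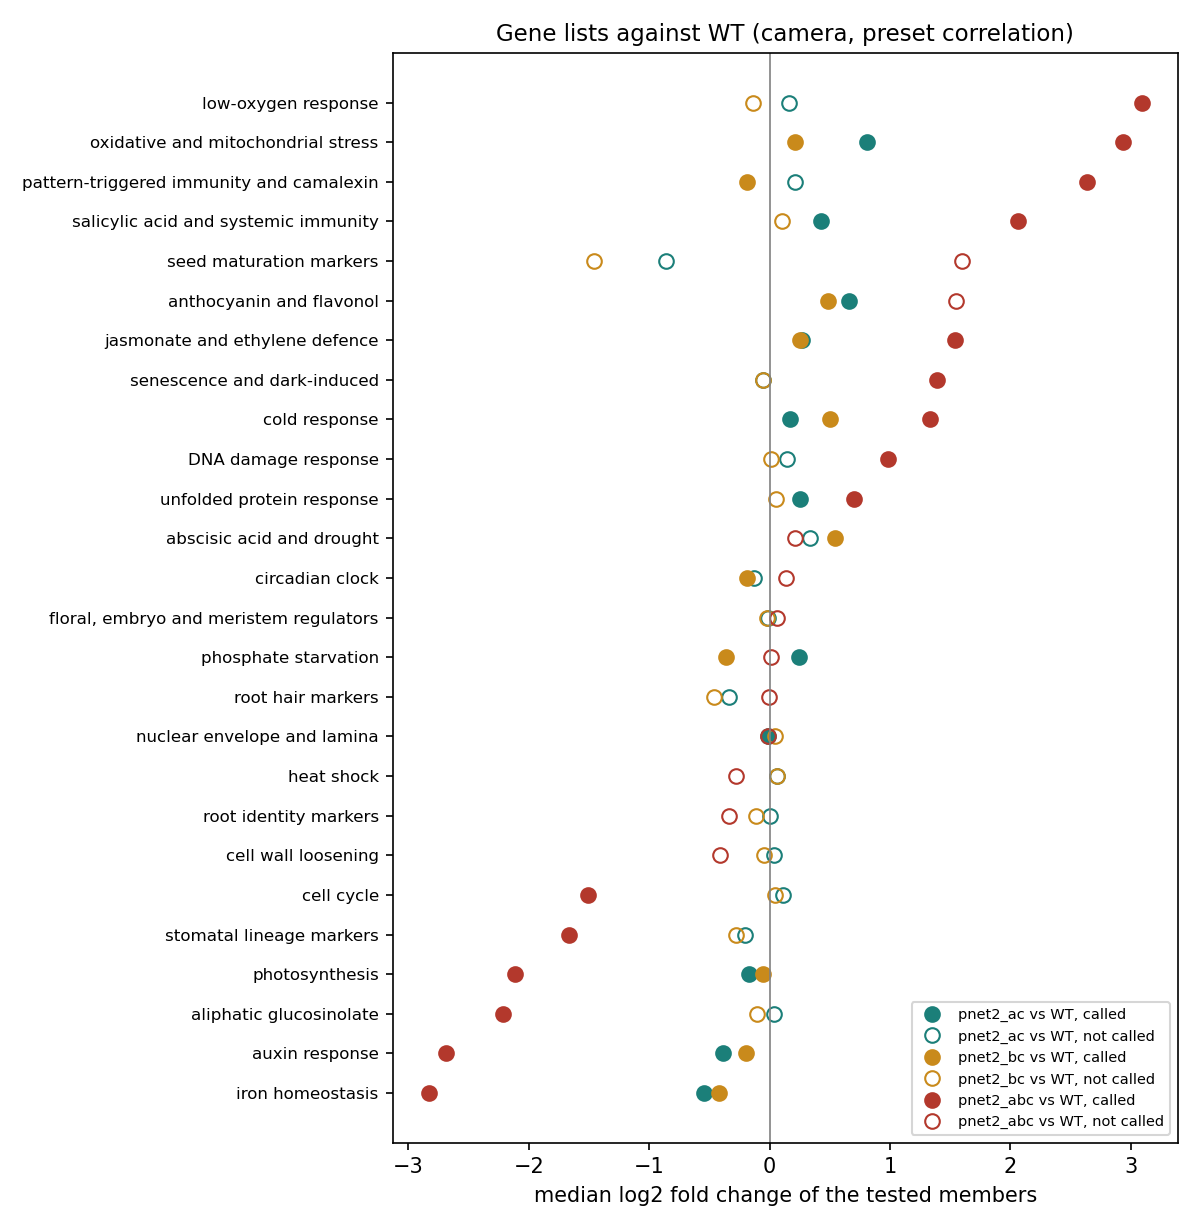
Median log2 fold change against WT (horizontal axis) of the tested members of each gene list (vertical axis) in pnet2_ac, pnet2_bc and pnet2_abc; filled points passed camera with the preset correlation and open points did not, and no list passed with an estimated correlation. The photosynthesis list lies at -2.11 in pnet2_abc and at -0.17 and -0.06 in pnet2_ac and pnet2_bc.

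Some genes were nearly off in one genotype and abundant in another. AT3G29970, a B12D protein gene, AT1G70390, an F-box protein gene, and XTH11 had no count in WT and reached 83.9 ± 14.4, 29.9 ± 2.32 and 21.5 ± 0.94 CPM in pnet2_abc, at least 6130-fold, 2185-fold and 1568-fold higher against a floor of 3 counts over the 3 WT libraries. ELI3-2, a cinnamyl alcohol dehydrogenase gene, and AT5G55410 reached 30.4 ± 6.01 and 20.02 ± 4.30 CPM from 4 and 3 counts in all of WT, and AT4G12735 reached 42.4 ± 3.599 CPM from 9 counts. TPS-CIN (AT3G25830), a cineole synthase gene, went from 77.4 ± 12.9 CPM to no count, at least 5851-fold lower, but its transcript is identical to that of AT3G25820, so how reads were divided between the pair is uncertain, and it also had no count in pnet2_bc replicates 2 and 3 but 83.6 CPM in replicate 1. AT3G25820 itself fell (log2 fold change -1.78). A thionin gene, AT1G66100, fell 482-fold, AT1G13650 130-fold, the subtilase gene AT4G21650 95.7-fold, AT3G28220 87.1-fold and the aldolase gene FBA5 61.7-fold.

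The triple mutant was also compared directly with each double mutant, in which by the labels 1 of the 3 genes is not mutated. Whether the lines carry the same alleles is not given, and AT1G28760 (5.33 and 4.44 CPM in the double mutants, 47.4 CPM in pnet2_abc) and AT3G49840 (6.69, 6.81 and 2.17 CPM) were called against WT in pnet2_abc alone. The test called 14672 genes against pnet2_ac (7156 higher, 7516 lower) and 14943 against pnet2_bc (7416 higher, 7527 lower), and with the unfiltered TPM values 59.5% and 60.4% of calls were higher, against 48.8% and 49.6%. Against pnet2_ac, ICL, the isocitrate lyase of the glyoxylate cycle, was 172-fold higher at 344 ± 80.6 CPM, and RRTF1, which overlaps antisense genes, was 170-fold higher. AT3G29970 and AT1G70390 were 2919-fold and 801-fold higher than in pnet2_ac, where they had 7 and 9 counts. AT1G66100, AT1G13650 and AT3G28220 were 466-fold, 128-fold and 107-fold lower, and TPS-CIN was at least 5755-fold lower. Against pnet2_bc, AT3G29970 was at least 6293-fold higher, XTH11 513-fold, AT4G12735 390-fold and AT5G55410 365-fold. AT1G66100, AT3G28220, AT1G13650 and AT4G21650 were 909-fold, 180-fold, 147-fold and 105-fold lower. All 16 of these calls held in each alternative that gave the gene a value. TPS-CIN had no value against pnet2_ac in DESeq2's Wald test.

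The double mutants differed from each other in 60 called genes, 30 higher and 30 lower in pnet2_bc, 17 of them at least 2-fold. WIP1 was 15.6-fold lower in pnet2_bc (log2 fold change -3.97 ± 0.12, adjusted p = 3.2e-09) and MRD1 was 86.6-fold lower (-6.44 ± 0.37, adjusted p = 3.8e-06). AT3G22121 was 12.1-fold lower and RLP22, a receptor-like protein gene, was also lower (log2 fold change -1.68). RLP22 stood at 0.869 to 1.21 CPM in pnet2_ac and 0.216 to 0.497 CPM in pnet2_bc. RLP22 and AT1G29785 reached the mean of 5 CPM needed for naming only through pnet2_abc. AT1G61690, AT1G29785, MYBL2 and AT1G62510, which overlaps an antisense gene, were 3.76-fold, 4.60-fold, 2.25-fold and 2.14-fold higher. The calls for WIP1, MRD1 and AT1G61690 held in every alternative, and with library size alone 38.2% of the called genes were higher, against 50.0% of the 60. Leaving out 1 library changed this count to 132, 8 and 11 without pnet2_ac replicates 1, 2 and 3, to 14, 21 and 28 without pnet2_bc replicates 1, 2 and 3, and to 28, 28 and 31 without WT replicates 1, 2 and 3. The counts against WT likewise fell to 79, 90, 59, 91, 129 and 71 for pnet2_ac without WT replicates 1 to 3 and pnet2_ac replicates 1 to 3, and to 60, 46, 45, 41 and 29 for pnet2_bc without WT replicates 1 to 3 and pnet2_bc replicates 1 and 2.

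Genes called in more than one mutant mostly moved the same way in the double mutants. Of the called genes, 24 rose and 29 fell in both pnet2_ac and pnet2_bc (0.3 and 0.6 for independent lists, which these are not, since they share the WT libraries), and 1 went opposite ways, MRD1. Between pnet2_ac and pnet2_abc 72 rose and 134 fell in both (34.1 and 51.5 for independent lists) and 27 went opposite ways. For pnet2_bc and pnet2_abc 36 rose and 38 fell in both (22.8 and 25.6) and 54 went opposite ways, among them WRKY33 and STZ, both lower in pnet2_bc and higher in pnet2_abc. Across the 23330 genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.655 for pnet2_ac and pnet2_bc, 0.418 for pnet2_ac and pnet2_abc and 0.263 for pnet2_bc and pnet2_abc, against 0.497, 0.498 and 0.494 in 20 simulations with no effect and the same WT libraries. The simulated mutants had WT means, so their r arises from the shared WT libraries alone. Real changes in a mutant widen its spread of fold changes and can lower r. An r below the simulated value therefore does not show that mutants share less than unchanged genotypes. The covariances were 0.402, 0.594 and 0.384, above the simulated ones by 0.309, 0.49956 and 0.290. Genes without a count in WT were simulated as absent from every library, so they enter the real values but not the simulated ones. These differences may therefore be overstated. Genes with low counts carry much of the covariance: with a mean of at least 5 CPM the covariances were 0.0443, 0.161 and 0.0555, above the simulated ones by 0.0277, 0.144 and 0.0392. Because 3 WT libraries are too few to split, how much of the overlaps comes from the shared controls is not known.

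Since PNET2 proteins lie in the nuclear membrane, the positions of the called genes were examined. Within 3 Mb of the estimated centromere centres 62.9% of 1930 tested genes were called in pnet2_abc, against 64.9% of 21245 elsewhere (two-sided Fisher's exact test, p = 0.0816, Benjamini-Hochberg adjusted p = 0.346 over the 6 comparisons). By the same Fisher's exact test the shares were 1.35% and 1.13% in pnet2_ac (p = 0.372, adjusted p = 0.558) and 0.67% and 0.64% in pnet2_bc (p = 0.882, adjusted p = 1). With limits of 2 and 5 Mb and Fisher's exact test the odds ratios in pnet2_abc were 0.849 (p = 0.0439) and 0.895 (p = 0.00049), beside 0.917 at 3 Mb, and for calls of at least 1 log2 unit at 3 Mb the odds ratio was 1.001 (p = 1). The called share per chromosome in pnet2_abc lay between 63.95% and 65.95%. Neighbouring tested genes were called in the same direction in 5546 of 23170 pairs in pnet2_abc, against a mean of 4854.2 over 10000 permutations of the calls (p = 0.0001, the smallest they can give). Against the double mutants the triple mutant gave 5258 pairs (4615.4 permuted) and 5437 (4779.9), both with permutation p = 0.0001. Against WT there were 2 such pairs against 1.6 permuted in pnet2_ac (permutation p = 0.4695) and 1 against 0.5 in pnet2_bc (p = 0.3799), and between the double mutants 2 pairs were called, against 0.1 (p = 0.0032). Neighbours that overlap on the same bases were counted as pairs, and reads shared between them can produce such a pair. MRD1 and AT3G22121, both called lower in pnet2_bc than in pnet2_ac, overlap tested antisense genes. How many pairs arise in this way was not tested, so the pair counts alone do not show clustering by position. Genes within a library are not independent, so these p-values describe these libraries.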

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

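The counts of called genes in pnet2_abc moved little: leaving out 1 library gave 14130 to 15165 against WT, 13708 to 14842 against pnet2_ac and 13888 to 15120 against pnet2_bc. The smaller counts moved by over 1.5 times. With 1 library left out, the 266 genes in pnet2_ac became 79, 90 and 59 without WT replicates 1, 2 and 3, 91, 129 and 71 without pnet2_ac replicates 1, 2 and 3, and at most 294, without pnet2_abc replicate 3. The 150 genes in pnet2_bc became 60, 46 and 45 without WT replicates 1, 2 and 3, 41 and 29 without pnet2_bc replicates 1 and 2, and at most 200, without pnet2_ac replicate 1. The 60 genes between the double mutants became 28, 28 and 31 without the WT replicates, 132, 8 and 11 without the pnet2_ac replicates and 14, 21 and 28 without the pnet2_bc replicates. DESeq2's Wald test gave 1101, 680 and 517 genes for these 3 comparisons, and the TPM values without a filter 173, 71 and 24. TPM with a pseudocount of 1 gave 409 in pnet2_ac, and the 6 libraries alone gave 249 in pnet2_bc. Leaving out WT replicate 1 and pnet2_ac replicate 2 together, chosen after the data were seen, gave 17, 67 and 11. The share of higher genes was 26.9% in pnet2_ac with only 6 libraries, and 63.6% between the double mutants, where leaving out those 2 libraries left 2 of 11 genes higher. The cause was not tested.

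With genes of at least 5 CPM, r was 0.615 for pnet2_ac and pnet2_bc, 0.442 for pnet2_ac and pnet2_abc and 0.163 for pnet2_bc and pnet2_abc. The spread of r was taken from the simulated range divided by 4. By Fisher's exact test, odds ratios for genes near the centromeres with limits of 2 and 5 Mb were 0.8487 (p = 0.0439) and 0.8951 (p = 0.000487) in pnet2_abc against WT, 0.8289 (p = 0.0203) and 0.9055 (p = 0.00161) against pnet2_ac, and 0.851 (p = 0.049) and 0.9361 (p = 0.0375) against pnet2_bc. For calls of at least 1 log2 unit they were 1.001 (p = 1), 1.035 (p = 0.506) and 1.056 (p = 0.279) by the same exact test. Rises of at least 1 log2 unit against pnet2_bc went the other way, with an odds ratio of 1.159 (Fisher's exact test, p = 0.0213). No called result changed its direction while still called. A result called in neither fit was counted as unchanged whatever its sign. The call for AT5G67610 in pnet2_bc ended in 10 of 24 alternatives, also with library size alone (0.0525), with the 2 libraries left out (0.121) and with TPM (0.0574, 0.0636 and 0.0894). Those 2 libraries also ended the calls in pnet2_bc for oxidative stress (0.254), auxin (0.0808) and the clock (0.0545). Estimated correlation ended 11, 11 and 15 list calls in pnet2_ac, pnet2_bc and pnet2_abc. Some lists not called became called in alternatives, most often senescence in pnet2_ac (9 of 20, adjusted p 0.00039 to 0.287) and low oxygen in pnet2_bc (5 of 20, 0.00118 to 0.885).

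The replicate number was also fitted as a block, although the labels do not say that equal numbers belong together. Counts with the block were 229, 166 and 14939 against WT for pnet2_ac, pnet2_bc and pnet2_abc, 14614 and 14803 for pnet2_abc against pnet2_ac and pnet2_bc, and 87 between the double mutants. The block ended the call of the nuclear envelope list in pnet2_ac (0.535) and the oxidative stress list in pnet2_bc (0.0704) and added the low-oxygen list in pnet2_bc (0.0307), and it ended no other list call. Similar totals hid some turnover. With the block, 195 of the 266 calls in pnet2_ac, 119 of the 150 in pnet2_bc and 51 of the 60 between the double mutants were kept. Over 18 pairs of libraries with the same number in different groups, correlations of the residuals ran from -0.028 to 0.072 (median 0.014). Of 12 libraries, 9 correlated best with their own number, so a batch shared by equal numbers is not excluded.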

Other observations

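The tests of scaling, green tissue and harvest time for the photosynthesis genes were chosen only after their result was seen.

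Of the 15 clock genes with a morning or evening phase, 11 were called in pnet2_abc, although the clock list did not pass. CCA1, LHY, RVE8 and RVE1 fell, with log2 fold changes of -1.61, -1.29, -1.64 and -4.54, as did LNK1 (AT5G64170, -1.22) and LNK2 (AT3G54500, -1.60), while PRR9 rose (0.50). Evening genes TOC1 (0.74), PRR5 (3.69), GI (0.44) and ELF4 (1.04) rose, and ELF3, PCL1, BOA and FKF1 were not called. Over 7 morning genes the median was -1.60 (SE 0.70) and over 8 evening genes 0.59 (SE 0.57), and under the other scalings the morning median lay between -1.59 and -1.38. In pnet2_ac and pnet2_bc, RVE1 had log2 fold changes of -0.60 (adjusted p = 0.0397) and -0.56 (adjusted p = 0.0692).

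The 6 libraries of each comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Only 1 of the 10 splits, the real one, gave as many genes in each comparison. Every other split puts libraries of both genotypes into each group, so a real difference adds to the spread and lowers the count. The other counts therefore do not show how many genes splits of unchanged libraries would call. Real count and highest other were 266 and 4 for pnet2_ac against WT, 150 and 3 for pnet2_bc against WT, 15054 and 1 for pnet2_abc against WT, 14672 and 1 for pnet2_abc against pnet2_ac, 14943 and 0 for pnet2_abc against pnet2_bc, and 60 and 2 for the double mutants.

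All 46 photosynthesis genes fell in pnet2_abc, with a median log2 fold change of -2.11. The choice among the 6 scalings run does not account for the fall, since the list median closest to 0 over them was -1.90. They lay close together, with a median of all genes of 0.011 under TMM and 0.205 with library size alone. They could therefore not have brought the list near 0. All 6 are relative to the reads of a library, so scaling in general is not decided. A smaller share of green tissue stays open: 22 root markers, which that would raise, had a median of -0.10 (SE 0.22), so they moved neither way by more than their spread. Another harvest time of day also stays open, since morning genes had a median of -1.60 and evening genes 0.59, and the labels give no hour. The genotype, with slower growth or a stress response as routes, may be the cause as a hypothesis. Seedlings of all genotypes harvested at the same recorded hour would test the harvest time only. They would not tell these routes from each other or from a smaller share of green tissue.

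WIP1 rose 15.9-fold in pnet2_ac and was 15.6-fold lower in pnet2_bc than in pnet2_ac. Reads shared with a near-identical gene are argued against, with 0 other transcripts at 95% identity over 80% of the length, and so is a changed stretch of chromosome around the gene, since 0 of 29 tested neighbours within 50 kb were called higher. The log2 fold changes of these uncalled neighbours ran from -1.44 (AT4G26390) to 4.55 (AT4G26460, downstream of WIP1, edgeR adjusted p = 0.419). An insertion or a background variant at WIP1 itself was not tested, and it cannot be seen in counts per gene. One hypothesis is that the pnet2_ac line carries such a variant, and another that mutation of A and C may raise WIP1, although its log2 fold change in pnet2_abc was 0.40. Reads over the WIP1 locus would test the first, and a second line with mutations in A and C the other.

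AT1G28760, of the targeted family, rose 11.9-fold in pnet2_abc while the other 2 family members fell, and it had 5.33 and 4.44 CPM in pnet2_ac and pnet2_bc (adjusted p 0.154 and 0.750), against 3.97 CPM in WT. Reads shared with a near-identical gene are argued against (0 other transcripts), and so are reads from an overlapping or adjoining gene, since 0 of 2 such genes were called higher by at least as much. A transcript driven from an inserted sequence could not be told from one of the intact gene here. As a hypothesis, the pnet2_abc line may carry an allele of AT1G28760 that is transcribed more than the intact gene, and reads over the locus would test it. By the labels each of A, B and C is mutated in at least 1 double mutant, so an allele shared by the lines would have to be raised in the triple mutant alone, which was not tested.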
